A study of Mus musculus with 6 samples.

How the data were processed

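Mouse lung fibroblasts that carry a green fluorescent reporter driven by the Col1a2 promoter were transduced by retrovirus, per the labels' protocols, with an inducible active, truncated form of Srebf1c (trSrebf1) or with a control vector. The vector marker was hLNGFR, a human cell surface receptor. Cells were placed in the airways of bleomycin-treated mice and later recovered by sorting live cells that were positive for the reporter and the marker and negative for CD31, CD45, EpCAM, CD146 and Ter119. PolyA RNA from 10000 sorted cells per library was amplified on beads and sequenced by 3'SAGE-seq on an Ion Proton, a method that reads a short tag near the 3' end of a transcript. There were 3 control and 3 trSrebf1 libraries.

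The deposited tables hold whole-number counts per gene symbol, 1 table per library, with the same 19865 symbols in the same order and no symbol repeated. Each symbol had at least 1 count in at least 1 library. Bowtie2 2.2.5 and the genome build mm10 are named, with no role or order, per the submitters' processing notes. The counting tool, the gene annotation and the use of strand are not given in the sources used here. A tag that matches several loci can therefore be split or dropped in ways that cannot be checked from the counts, and values of near-identical genes and of genes with overlapping exons are uncertain. No gene model of the transgene or of the reporter was used here.

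Library totals ranged from 3675146 to 4688196 counts. Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total count 15), robust glmQLFit and glmQLFTest, a model with the group as its only term, and a two-sided threshold of 0.05 on p-values adjusted by the Benjamini-Hochberg method over the 10194 genes that passed the filter. Fold changes carry a prior count of 0.125, and the standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values, which scale the counts of a library to a common total, were computed with the TMM-scaled library sizes. For a gene with 0 counts in all control libraries, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 control counts, the ratio is given with an exact (Clopper-Pearson) 95% interval of the share of counts. These bounds and intervals cover counting error only, since amplified tags without molecular identifiers are not independent molecules.

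The labels do not say whether the 3 replicates of a group came from separate mice or cultures. The p-values therefore measure the spread between these libraries, which may be technical. Within a group, pairs of libraries differed by 4.52 to 8.13 times the chi-square per degree of freedom that sampling of counts gives, over genes with 10 or more counts, so no library was treated as a second copy of another. Ctsd took 0.92% ± 0.05 of the counts in control and 6.71% ± 0.16 in trSrebf1 libraries (SD, n = 3 each).

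A total of 27 gene lists (fatty acid synthesis, cholesterol synthesis and uptake, liver X receptor (LXR) targets, collagens and matrix, contractile and myofibroblast genes, transforming growth factor beta (TGF-beta) response, matrix proteases and inhibitors, resident and lipofibroblast genes, cell cycle, inflammatory mediators, interferon response, unfolded protein and integrated stress response, glycolysis and hypoxia, fatty acid oxidation and peroxisome, oxidative phosphorylation, NRF2 and oxidative stress, p53 with senescence and apoptosis, dissociation and immediate early genes, mitochondrially encoded genes, and markers of 8 other cell types) were fixed before the data were examined, as were the tests and the alternative settings other than leaving out Ctsd. The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 22 lists with 5 or more tested members. Beside it, camera with an estimated correlation and fry were run. Camera compares a list with all other genes. Fry asks whether the members of a list move, on balance, in 1 direction. Of the mitochondrially encoded genes, 0 of 13 symbols matched a row of the tables, and that list was not analysed here. Members shared with another list were 3 or fewer in each of the 27 lists.

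Named genes followed a rule fixed before the data were examined. Srebf1, Col1a1, Col1a2, Acta2, Scd1 and Fasn were named in any case. Of the genes past the threshold whose groups did not overlap and whose higher group averaged 20 CPM or more, the 10 largest rises and the 10 largest falls were named, leaving out symbols made of Gm, Rik, LOC, BC or AI with digits. For each biology or quality list up to 4 members with the smallest unadjusted p were named, and for each list of other cells the 2 members with the highest mean CPM and any member past the threshold. The rule gave 123 genes, and Acacb, Mvk, Pdlim7, Rrm1 and Tgfb1, each among 5 or fewer members of a list that are counted apart, were chosen after their values were seen. Some genes that the rule gave are not reported here. Any other gene outside the rule is marked so where it is named.

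Positions come from GENCODE M21 on GRCm38, the assembly that mm10 names, counted from 1. Symbols were matched directly or through RefSeq synonyms, which placed 96.1% of the tested genes and all 123 named genes. Of the named genes, 31 have exons that overlap an exon of another gene, 3 of them on the same strand, and 8 match another gene at 95% identity over 100 or more of the last 500 transcript bases (BLAST 2.17.0).

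The test was checked on counts simulated from the means and library sizes of these 6 libraries with 200 changed genes among 10194. It called 18%, 62%, 96% and 98% of genes changed by 1.5, 2, 4 and 8 fold, and 11.6% of its 155 calls were unchanged genes, above the nominal 5%. With no change simulated it called 1 of 10194 genes and 1 of 21 lists. With the contractile list alone lowered by 0.5 on the log2 scale it called that list and no other of 22. Each gene was simulated independently, so these checks cannot show how often lists are called wrongly when their members vary together. The alternatives were other scaling factors (RLE, upper quartile, total counts), DESeq2 1.42.0 (Wald test), limma-voom with sample weights, no filter on low counts, a filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and Ctsd left out.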

Results

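The transcriptomes of transferred lung fibroblasts were measured by 3'SAGE-seq in 6 libraries, 3 from cells carrying the control vector and 3 from cells carrying trSrebf1, the active form of the lipid-synthesis transcription factor Srebf1. Mice received 2 mg/kg of bleomycin, a drug that injures the lung and leads to fibrosis. On day 5 the transduced cells were placed in the airways. Doxycycline, which switches on trSrebf1, was given from day 7, a day recorded for the libraries of both groups. Donor cells were sorted on day 10. Control libraries held 3888560, 3675146 and 4134354 counts and trSrebf1 libraries 4688196, 4151691 and 4504005. The comparison asks how the active form of Srebf1 alters the transcriptome of fibroblasts within an injured lung.

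Tags of Srebf1 (chromosome 11, 60199089 to 60222581, minus strand) were counted first, as a check of the labels. They numbered 32, 20 and 33 in the control libraries and 133, 123 and 108 in the trSrebf1 libraries. Expression rose from 7.11 ± 1.72 to 28.2 ± 3.30 CPM (SD, n = 3 each), a log2 fold change of 1.98 (SE 0.23, adjusted p = 2.88e-06). The transgene is truncated, and the 3' end that the assay counts may lie outside it, so these tags may come from the endogenous gene, the transgene or both. The last exons also overlap an exon of Rai1 on the opposite strand over 109 bases.

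Of 10194 tested genes, 1755 were higher and 1328 lower in trSrebf1 than in control fibroblasts (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The change was over 1 on the log2 scale for 974 of the higher and under -1 for 596 of the lower genes. It was over 3 for 181 higher genes and under -3 for 10 lower genes. The libraries of the 2 groups did not overlap for 3001 of the 3083 called genes, and for 43.4% of all tested genes where chance gives 10%. The median log2 fold change of all tested genes was -0.01.

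**Figure D1:**
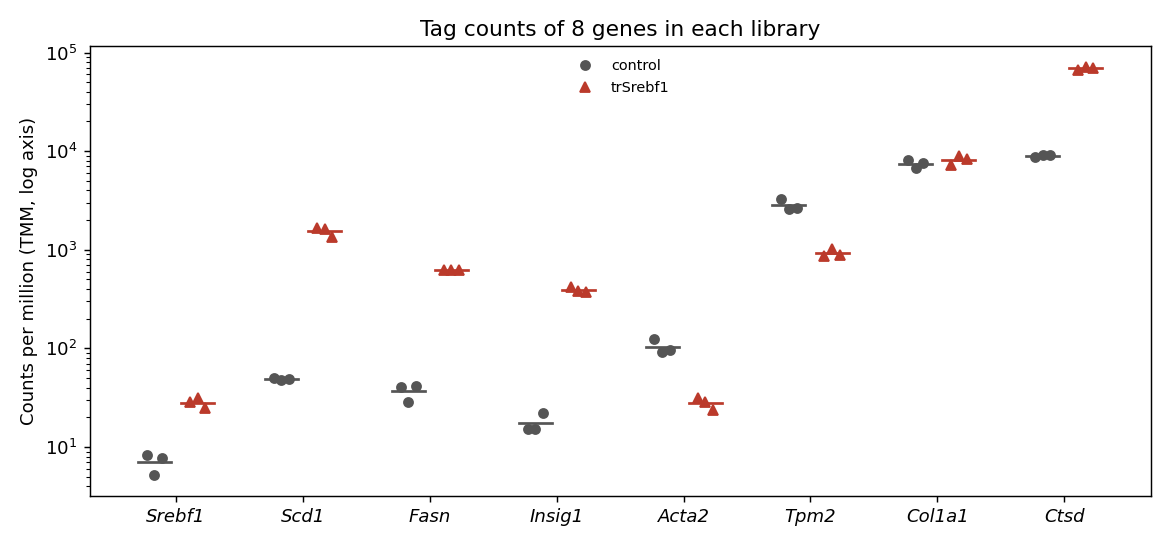
CPM (log axis) of 8 genes in each library, with 3 control libraries as grey circles, 3 trSrebf1 libraries as red triangles and the mean of each group as a line. Scd1, Fasn and Insig1 lie higher and Acta2 and Tpm2 lower in all 3 trSrebf1 libraries, while the 2 groups overlap for Col1a1.

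Of the 22 gene lists tested, 12 passed the camera test at the preset correlation, 4 higher and 8 lower, and 2 passed with an estimated correlation. Splits of the libraries that mixed both groups passed as many as 12 lists at the preset correlation. Such splits keep part of the difference between the groups, so that count is not the level that chance alone gives.

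Genes of fatty acid synthesis rose together. Of 23 tested members 22 rose and 1, Acacb, did not pass the threshold, and 23 rose when adjusted over the list alone. Acacb passed it without control replicate 3 (adjusted p = 0.0379), without trSrebf1 replicate 1 (0.00928) and with no filter on low counts (0.00999), in a range of 0.00928 to 0.350 over the alternatives. The median log2 fold change was 2.03 (camera adjusted p = 1.87e-33, and adjusted p = 0.00405 with an estimated correlation). Scd1 (chromosome 19, 44394455 to 44407879), the desaturase that makes monounsaturated fatty acids, rose 31.5-fold from 49.1 ± 1.34 to 1548 ± 166 CPM (SD, n = 3 each). Fasn, the fatty acid synthase, rose 16.7-fold from 37.3 ± 7.27 to 622 ± 3.72 CPM, and Acly, which supplies cytosolic acetyl-CoA, rose by 3.77 on the log2 scale (SE 0.11). Scd2 rose by 2.76 (SE 0.14), and since the 3' ends of Scd1 and Scd2 match over 500 bases in some transcripts, the split of tags between the pair is uncertain.

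Cholesterol synthesis and uptake genes rose to a like extent, with a median log2 fold change of 1.95. Of 25 tested members 22 rose and 0 fell, and adjusted over the list alone 22 rose and 1, Mvk, fell (camera adjusted p = 6.15e-37, and adjusted p = 0.0218 with an estimated correlation). Over all genes Mvk fell past the threshold without control replicate 2 (adjusted p = 0.0268), with upper-quartile factors (0.0317) and with total counts (0.0246), in a range of 0.0246 to 0.337 over the alternatives. Insig1, which retains the SREBP precursors in the endoplasmic reticulum, rose by 4.47 on the log2 scale (SE 0.15) to 392 CPM. The synthesis enzymes Lss and Nsdhl rose by 3.70 (SE 0.15) and 2.37 (SE 0.11). Tm7sf2 rose by 4.39 (SE 0.13), but shares exonic sequence with Vps51 on the same strand, so its value is uncertain.

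The LXR target list did not pass the test (camera adjusted p = 0.983), with 2 members higher and 2 lower of 10, and the same counts adjusted over the list alone. Its median of -0.19 and mean of -0.00 lay below 0 while the direction given by camera was up. The phospholipid enzyme Lpcat3 rose by 2.09 (SE 0.21) and the lipid transfer protein Pltp by 1.04 (SE 0.16) on the log2 scale. The apolipoprotein Apoe fell by 2.19 (SE 0.23), and Nr1h3, which encodes LXR alpha, had a log2 fold change of -0.41 (SE 0.15, adjusted p = 0.0464), with exonic sequence shared with another gene on the same strand. The call of Nr1h3 was lost under the DESeq2 Wald test (adjusted p = 0.0725) and limma-voom (0.0636). It was also lost without control replicate 1 (adjusted p = 0.222), control replicate 3 (0.0599), trSrebf1 replicate 1 (0.118) or trSrebf1 replicate 3 (0.151), in a range of 0.0168 to 0.222 over the alternatives.

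Contractile and myofibroblast genes fell. Of 28 tested members 22 fell and 2, Des and Pdlim7, rose, the call of Des being lost without control replicate 3 (adjusted p = 0.0551) and without trSrebf1 replicate 3 (0.0630), in a range of 0.00504 to 0.0630 over the alternatives. The call of Pdlim7 was lost without control replicate 2 (0.179), control replicate 3 (0.115), trSrebf1 replicate 1 (0.0770) or trSrebf1 replicate 2 (0.164), with upper-quartile factors (0.0922), total counts (0.0709) and DESeq2 (0.0752), in a range of 0.0155 to 0.179. Adjusted over the list alone 25 fell and 2 rose. The median log2 fold change was -0.92 (camera adjusted p = 6.72e-13), a call that was lost with an estimated correlation (adjusted p = 0.122). Acta2 (chromosome 19, 34241090 to 34255590), the smooth muscle actin used as a myofibroblast marker, fell by 1.89 on the log2 scale (SE 0.16), from 104 ± 18.0 to 28.0 ± 3.68 CPM (SD, n = 3 each). The tropomyosins Tpm2 and Tpm4 fell by 1.63 (SE 0.12) and 1.25 (SE 0.11), and the actin Actg2 fell by 1.39 (SE 0.10). In the same libraries the summed markers of pericytes and smooth muscle stood at 375 CPM in control and 510 CPM in trSrebf1. Of 10 tested members 3 rose and 5 fell (median -0.81), in cells sorted as negative for CD146, a pericyte marker. The sum therefore does not measure the share of pericytes.

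Collagen and matrix genes were mostly lower, with 26 of 48 members lower and 6 higher, and 28 lower and 7 higher when adjusted over the list alone. The median was -0.42 (camera adjusted p = 1.81e-04, and adjusted p = 0.524 with an estimated correlation). Col1a1 did not pass the threshold, at 7453 ± 707 CPM in control and 8123 ± 893 in trSrebf1 (SD, n = 3 each, adjusted p = 0.419). Col1a2, whose promoter drives the reporter used in the sort gate, fell by 0.47 (SE 0.10, adjusted p = 0.00157). The proteoglycan Dcn fell by 1.13 (SE 0.10), elastin (Eln) by 1.40 (SE 0.14) and fibrillin (Fbn1) by 1.11 (SE 0.11). Spp1, which encodes osteopontin, rose by 2.54 (SE 0.12).

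TGF-beta response genes were lower as a list, with 15 of 23 members lower and 2 higher by both adjustments, over all genes and adjusted over the list alone (median -0.58, camera adjusted p = 2.73e-04, and adjusted p = 0.284 with an estimated correlation). Ltbp2 fell by 0.97 (SE 0.11) and the cadherin Cdh11 by 0.87 (SE 0.12). Tgfbi rose by 2.71 (SE 0.26), and the ligand Tgfb1, named after its values were seen as the other member that rose, rose by 0.87 (SE 0.15). Among matrix proteases and inhibitors 12 of 21 were lower and 3 higher, and adjusted over the list alone 12 were lower and 4 higher (median -0.67, camera adjusted p = 0.0383, and adjusted p = 0.531 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0511), without trSrebf1 replicate 3 (0.0963) and under the filter of 5 CPM in 3 libraries (0.191), in a range of 0.00737 to 0.531 over the alternatives. Mmp23 fell by 1.22 (SE 0.15) and the gelatinase Mmp2 by 0.78 (SE 0.11), whereas the other gelatinase Mmp9 rose 27.9-fold from 2.06 ± 0.87 to 59.1 ± 5.72 CPM (SD, n = 3 each).

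Resident and lipofibroblast genes were lower as a list, with 9 of 17 lower and 2 higher by both adjustments, over all genes and adjusted over the list alone (median -0.95, camera adjusted p = 0.0163, and adjusted p = 0.17 with an estimated correlation). Itga8, Wnt2 and Limch1 fell by 2.07 (SE 0.23), 2.08 (SE 0.44) and 2.33 (SE 0.23). Plin2, which coats lipid droplets, rose by 1.89 (SE 0.13) to 368 CPM. Cell cycle genes fell in 10 of 17 tested members and rose in 1, Rrm1, and adjusted over the list alone 13 fell and 1 rose (median -1.14, camera adjusted p = 0.00197, and adjusted p = 0.17 with an estimated correlation). Top2a fell by 1.26 (SE 0.22), and the mitotic spindle genes Tpx2 and Nusap1 by 1.40 (SE 0.34) and 1.35 (SE 0.32). The call of Rrm1 was lost without control replicate 1 (adjusted p = 0.113), control replicate 3 (0.0795), trSrebf1 replicate 2 (0.0578) or trSrebf1 replicate 3 (0.12497), with upper-quartile factors (0.0581), total counts (0.0660) and DESeq2 (0.0796), in a range of 0.0352 to 0.12497.

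Inflammatory mediators fell in 18 of 23 members and rose in 3 by both adjustments, over all genes and adjusted over the list alone (median -1.06, camera adjusted p = 1.43e-05, and adjusted p = 0.122 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, fell by 1.88 (SE 0.20), the complement gene C3 by 1.67 (SE 0.19) and the interleukin receptor Il1r1 by 1.28 (SE 0.15). The adhesion molecule Icam1 rose by 1.67 (SE 0.11). The list of dissociation and immediate early genes, which respond to tissue digestion, moved with these groups. It was lower in 19 of 24 members and higher in 0 by both adjustments, over all genes and adjusted over the list alone (median -0.68, camera adjusted p = 1.92e-08, and adjusted p = 0.284 with an estimated correlation). Fosb fell by 0.99 (SE 0.11), Klf4 by 1.08 (SE 0.11), Klf2 by 1.26 (SE 0.15) and Btg2 by 1.41 (SE 0.16).

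**Figure D2:**
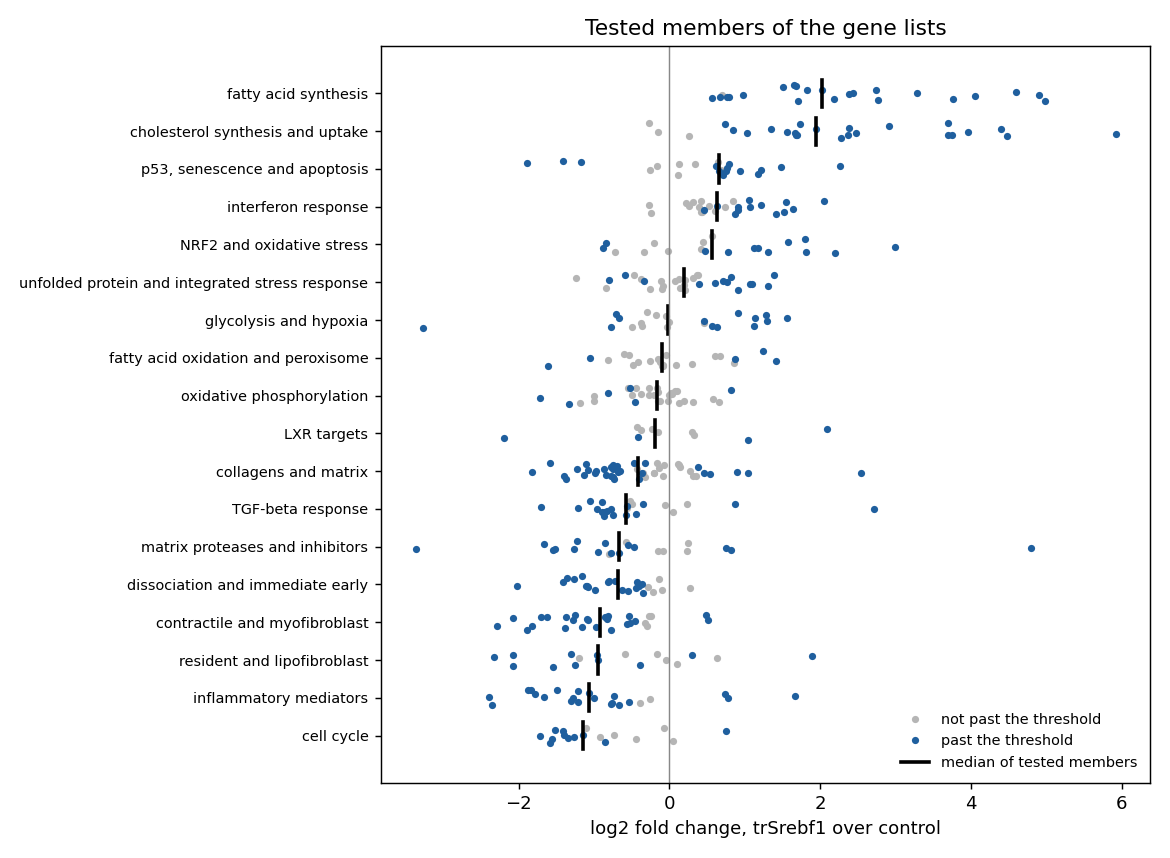
Log2 fold change (trSrebf1 over control) of each tested member of 18 gene lists, with genes past adjusted p 0.05 in blue, others in grey and the median of each list as a black bar. Medians run from -1.14 for the cell cycle to 2.03 for fatty acid synthesis.

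Interferon response genes rose in 13 of 27 members, and in 15 when adjusted over the list alone, with 0 lower by either adjustment (median 0.63, camera adjusted p = 9.99e-04, and adjusted p = 0.576 with an estimated correlation). Stat2 rose by 1.51 (SE 0.13), Ifit1 by 1.55 (SE 0.25) and Usp18 by 1.42 (SE 0.21). NRF2 and oxidative stress genes rose in 10 of 19 members and fell in 2 by both adjustments, over all genes and adjusted over the list alone (median 0.56, camera adjusted p = 0.0158, and adjusted p = 0.531 with an estimated correlation). The glutathione transferase Gstm1 rose by 1.82 (SE 0.24), mitochondrial superoxide dismutase (Sod2) by 1.18 (SE 0.12) and the ferritin light chain gene Ftl1 by 1.13 (SE 0.12). G6pdx, the first enzyme of the pentose phosphate pathway, rose by 1.80 (SE 0.25). Stat2, Ftl1, G6pdx and Sod2 have near-identical 3' sequence elsewhere in the annotation, so their values are uncertain.

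The other biology lists did not pass the camera test. In the list of p53, senescence and apoptosis 11 of 21 rose and 3 fell, and 12 rose and 3 fell when adjusted over the list alone (median 0.66, camera adjusted p = 0.0895). The call was gained without control replicate 3 (adjusted p = 0.0371), without trSrebf1 replicate 2 (0.0392), under limma-voom (0.0277), with no filter on low counts (0.0130) and under fry (0.0212), in a range of 0.0130 to 0.543 over the alternatives. The cell cycle inhibitor Cdkn1a rose by 1.48 (SE 0.11) to 6959 CPM and the death receptor Tnfrsf10b by 2.27 (SE 0.17), while Mcl1 fell by 1.18 (SE 0.16). Adjusted over the list alone, the unfolded protein and integrated stress list had 10 of 30 higher and 3 lower, glycolysis and hypoxia 9 of 22 higher and 4 lower, and fatty acid oxidation 3 of 22 higher and 2 lower, with the same counts over all genes. Their camera adjusted p-values were 0.509, 0.494 and 0.749. Oxidative phosphorylation had 1 of 31 higher and 5 lower, or 4 lower when adjusted over the list alone (adjusted p = 0.198). Within these lists Aldoa and Tpi1 rose by 1.14 (SE 0.10) and 1.12 (SE 0.16), Vegfa by 1.56 (SE 0.14), Mthfd2 by 1.39 (SE 0.24) and Ppard by 1.24 (SE 0.12). Aldoa has a near-identical copy. Slc2a1, a glucose transporter, fell by 0.71 (SE 0.11), and Decr1 by 1.61 (SE 0.28). Medians lay below 0 and the camera direction was up for glycolysis and hypoxia, and fry gave up where camera gave down for fatty acid oxidation.

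Markers of other cell types were summed in CPM per library, for 8 types. The sum for macrophages was 60.2 ± 33.1 in control and 41.3 ± 11.8 in trSrebf1, that for epithelium 105 ± 15.1 and 74.9 ± 33.4, and that for endothelium 264 ± 14.7 and 239 ± 7.02 (SD, n = 3 each). Sums were 9.88 and 9.38 for neutrophils, 127 and 107 for lymphocytes and 44.2 and 44.9 for mesothelium. Most of the lymphocyte sum came from Ccl5 (126 CPM in control and 105 in trSrebf1), which is also on the inflammatory mediator list. Csf3r gave most of the neutrophil sum (8.43 and 8.39 CPM). Sums that rest on 1 gene do not measure the share of such cells. Erythroid markers summed to 169 ± 42.0 and 94.3 ± 10.8, most of it from Bpgm, which fell by 0.91 (SE 0.16). Pericyte and smooth muscle markers summed to 375 ± 37.0 and 510 ± 26.2, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow, and 0.267 when adjusted over the 8 sums. The endothelial and erythroid sums, which were lower in trSrebf1, gave the same p of 0.1 and adjusted p of 0.267 in that exact test. Most of the endothelial sum came from Ecscr, at 202 CPM in control and 167 in trSrebf1 (edgeR adjusted p = 0.0598). Ecscr passed the threshold with upper-quartile factors, total counts and the filter of 5 CPM in 3 libraries, in a range of 0.0154 to 0.180 over the alternatives. Within the pericyte and smooth muscle list 3 of 10 members rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.711). Its sum held Postn, also on the matrix list, at 152 CPM in control and 132 in trSrebf1, Pdgfrb at 78.6 and 143, and Cspg4 at 16.4 and 121. That sum rests largely on a few genes and does not measure the share of such cells. Cspg4 and Pdgfrb rose by 2.87 (SE 0.21) and 0.86 (SE 0.12), while Lmod1, Kcnj8 and Ndufa4l2 fell by 1.37 (SE 0.22), 1.12 (SE 0.30) and 2.30 (SE 0.51). Without trSrebf1 replicate 2 the log2 fold change of Ndufa4l2 was -2.99 and that of Myh11, which fell by 1.14 (SE 0.42), was -1.73. Des, given above, was the other that rose, and Abcc9 and Myh11 were the others that fell. The call of Abcc9 was lost without control replicate 1 (adjusted p = 0.121), trSrebf1 replicate 2 (0.0806) or trSrebf1 replicate 3 (0.0604), in a range of 0.00339 to 0.121. The call of Myh11 was lost without control replicate 1 (0.108), control replicate 2 (0.187), trSrebf1 replicate 1 (0.202) or trSrebf1 replicate 3 (0.152), under DESeq2 (0.0721) and without Ctsd (0.0533), in a range of 0.00714 to 0.202.

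The camera adjusted p was 0.711 for macrophages, for epithelium and for endothelium as well. Adjusted over the list alone, macrophage markers had 1 of 5 members higher and 1 lower, epithelial markers 1 of 7 higher and 1 lower, and endothelial markers 2 of 5 higher and 2 lower, against 2 higher and 1 lower over all genes. Cd74 rose to 12.9 CPM and Tyrobp fell by 2.39 (SE 0.57) among macrophage markers (-3.59 without trSrebf1 replicate 3), Foxj1 rose to 6.21 CPM and Krt19 fell among epithelial ones, and Egfl7 rose to 6.65 CPM, Esam rose and Erg fell among endothelial ones. Egfl7 shares exonic sequence with another gene on the same strand, so its value is uncertain. The call of Krt19 was lost without control replicate 1 (adjusted p = 0.0804), control replicate 2 (0.0673), control replicate 3 (0.0719), trSrebf1 replicate 1 (0.0523) or trSrebf1 replicate 3 (0.0834), in a range of 0.00123 to 0.0834 over the alternatives. That of Esam was lost without control replicate 3 (0.104) or trSrebf1 replicate 1 (0.142) and under DESeq2 (0.0599), in a range of 0.0199 to 0.142. That of Erg was lost without control replicate 1 (0.0621), control replicate 2 (0.0887), trSrebf1 replicate 1 (0.0829) or trSrebf1 replicate 2 (0.0668) and under DESeq2 (0.0706), in a range of 0.0154 to 0.0887. The mesothelial list had 4 tested members, of which Slpi rose (2 counts in control and 134 in trSrebf1, ratio 61.6, 95% counting interval 16.7 to 514) and Krt19 fell by both adjustments, over all genes and adjusted over the list alone. The neutrophil, lymphocyte and erythroid lists had 1 tested member each, Csf3r, whose 3' end holds sequence found in other genes (log2 fold change -0.01, adjusted p = 0.987), Ccl5 (-0.26, adjusted p = 0.398) and Bpgm, and adjusted over the list alone only Bpgm was lower.

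The largest rises were of genes close to undetected in control cells. Ncan (chromosome 8, 70093085 to 70120873), a proteoglycan of the nervous system, had 0 counts in the 3 control libraries and 1624 in the trSrebf1 libraries, at least 498-fold higher. Bsnd had 0 and 574 counts, at least 176-fold higher. Duox2, Phyhip and Birc7 also had 0 control counts and were at least 113-fold, 109-fold and 92.3-fold higher. H2-Q10 had 1 and 930 counts (ratio 855, 95% counting interval 153 to 33824) and Nrarp 2 and 449 (ratio 207, interval 56.8 to 1710). The 1 control count of H2-Q10 came from control replicate 1, without which its fitted log2 fold change, a value that depends on the prior count, was 11.24 against 9.29. Bdh1, a ketone body enzyme, rose 245-fold from 1.10 ± 0.61 to 274 ± 9.85 CPM, and Prr18 rose 184-fold to 160 ± 17.2 CPM (SD, n = 3 each). Nrarp and Bdh1 exons overlap those of a gene on the opposite strand, and the 3' end of Prr18 holds sequence found in other genes.

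The largest falls were smaller on the log2 scale. Cemip, a hyaluronan-binding protein, fell by 4.14 (SE 0.79, adjusted p = 0.0212) from 178 ± 131 to 10.0 ± 2.90 CPM (SD, n = 3 each). Its call was lost without control replicate 1 (adjusted p = 0.0592), trSrebf1 replicate 1 (0.0914), trSrebf1 replicate 2 (0.0863) or trSrebf1 replicate 3 (0.0790), in a range of 7.01e-09 to 0.0914 over the alternatives. Without control replicate 2 the log2 fold change was -3.38. Wisp2 and Art4 fell by 3.12 (SE 0.28) and 3.03 (SE 0.25), and the Wnt antagonist Sfrp1 by 2.55 (SE 0.27). Fam46b, Figf and Fzd1 fell by 2.50 (SE 0.41), 2.46 (SE 0.31) and 2.43 (SE 0.56). The call of the Wnt receptor Fzd1 was lost without trSrebf1 replicate 1 (adjusted p = 0.0819) and without trSrebf1 replicate 2 (adjusted p = 0.0552), in a range of 9.52e-14 to 0.0819 over the alternatives, and without control replicate 2 its log2 fold change was -1.67. Hp, which encodes haptoglobin, fell by 2.35 (SE 0.28), and Igfbp4, a binding protein of insulin-like growth factors, by 2.34 (SE 0.14). In absolute level the largest gain was of Ctsd, a lysosomal protease chosen after its values were seen, from 9018 ± 236 to 69139 ± 2997 CPM (SD, n = 3 each). Whether tags of the vector or the transgene were assigned to Ctsd was not tested, since the vector sequence was not used here.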

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

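The alternative without Ctsd was chosen after the data had been seen. Over the 15 alternatives for counts of genes, higher genes numbered 1535 to 1977 and lower genes 1060 to 1649, within 1.5 times of 1755 and 1328, and 0 called genes were called in the opposite direction. Leaving out 1 library gave 1535 to 1734 higher genes, 1060 to 1230 lower genes and 11 to 13 lists. Upper-quartile factors moved the median log2 fold change of all genes from -0.01 to -0.10 and the share of higher calls from 56.9% to 48.5%. Of 109 called named genes 97 kept their call and direction under every alternative with a value. The replicate number as a block (replicate block) gave 1646 higher genes, 1174 lower genes and 12 lists, and the calls of Cemip and Nr1h3 were lost. Among genes named after their values were seen, it lost Pdlim7 (adjusted p = 0.0616, range over the alternatives 0.0155 to 0.179) and Rrm1 (0.0505, range 0.0352 to 0.12497) and gained Acacb (0.0392, range 0.00928 to 0.350). Deviations from the group means correlated at 0.00525, -0.112 and -0.0538 between libraries with the same number, so no strong shared effect was seen. These values cannot show whether libraries with the same number shared a mouse, a culture or a day. With an estimated correlation 2 of the 12 lists passed, since the correlation among members then widens the test, and fry passed 13.

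Directions changed for 5 lists and 5 genes, none of them past the threshold in any setting where they changed, and the cause was not tested. The direction of a list is the one camera or fry gives. The LXR target list turned from up to down with total counts (median log2 fold change -0.27), DESeq2 (-0.19), no filter (-0.18), 5 CPM in 3 libraries (-0.21), the replicate block (-0.16), without Ctsd (-0.18), and without control replicate 1 (-0.31) or trSrebf1 replicate 3 (-0.25), where leaving out 1 library gave -0.31 to 0.0058. The endothelial list turned with no filter (-0.27), the pericyte list with 5 CPM in 3 libraries (-0.37) and fatty acid oxidation with fry (-0.094). The epithelial list turned without control replicate 2 (-0.061) or control replicate 3 (-0.20), in a range of -0.64 to -0.061 without 1 library. Csf3r turned under limma-voom (0.0092), no filter (0.0014), without Ctsd (0.0076), and without control replicate 1 (0.061), control replicate 2 (0.042), trSrebf1 replicate 1 (0.091) or trSrebf1 replicate 3 (0.0099), in a range of -0.14 to 0.091 without 1 library. Without 1 library Upk1b ranged from -0.12 to 0.34 and turned without control replicate 1 (-0.081) or trSrebf1 replicate 3 (-0.12). Without control replicate 2, Ccl5 (0.045, range -0.43 to 0.045) and Cldn18 (0.21, range -0.78 to 0.21) turned, as did B2m, named after its values were seen (0.39, range -0.89 to 0.39). At 3675146 to 4688196 counts per library, the simulated test recovered 18% of genes changed by 1.5 fold, so a gene that is not called may still have changed by that much.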

Other observations

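The gene lists and single genes of this part, and the tests of other cell types, of Ctsd, of fewer fibroblasts and of a chromosome segment, were chosen after the results had been seen. Camera p-values of the lists chosen so were adjusted over those lists alone, not over the 22 fixed lists. Several of them hold genes already seen to rise, such as Ctsd, H2-Q10, G6pdx and Me1. Their p-values therefore describe the lists and give no independent support. Genes that present antigen on MHC class I rose, with 15 of 23 tested members higher and 0 lower (median log2 fold change 1.74, camera adjusted p = 1.62e-17, and adjusted p = 0.0556 with an estimated correlation). Of the 15, 11 are heavy chain genes, most of which share 3' sequence with copies, and the other 4 are Tap1, Tap2, Tapbp and Tapbpl, the last not past the threshold without trSrebf1 replicate 1 (adjusted p = 0.0647, range 0.00875 to 0.0647). The peptide loading genes Tapbp and Tap2 rose by 2.15 (SE 0.12) and 1.65 (SE 0.14). Tap1, Tap2 and Tapbp lie on chromosome 17 between 33 and 38 Mb, the segment treated below with the heavy chain genes. For them too, a segment that differs between the donor cells cannot be told apart from a response to trSrebf1. B2m, the light chain, was counted at 6.28 and 4.36 CPM and did not pass the threshold (log2 fold change -0.50, adjusted p = 0.539, and 0.39 without control replicate 2). It had 74 counts in control and 58 in trSrebf1, too few to show whether the light chain changed. Counts can differ widely within a family, as Rpl6 averaged 0.44 CPM and Rpl8 14134 CPM in control. How fully the assay captures B2m was not tested. A list of NADPH supply and pentose phosphate pathway genes rose in 7 of 14 members and fell in 2 (median 0.42, camera adjusted p = 0.00771, and adjusted p = 0.106 with an estimated correlation). Pgd rose by 2.16 (SE 0.12) and Me1 by 2.03 (SE 0.25), while Idh2 and Nnt fell by 1.70 (SE 0.35) and 1.37 (SE 0.47). The call of Nnt was lost without control replicate 2 (adjusted p = 0.133), control replicate 3 (0.0725), trSrebf1 replicate 1 (0.152) or trSrebf1 replicate 3 (0.136), in a range of 0.00149 to 0.152, and without trSrebf1 replicate 2 its log2 fold change was -2.30.

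Of 45 lysosomal genes, Ctsd among them, 17 rose and 6 fell (median 0.17). The camera adjusted p was 0.0364, the same as the unadjusted p, and 0.234 with an estimated correlation. Tags counted as Ctsd rose 7.67-fold, although whether some came from the vector or transgene was not tested. Of the other members Neu1 rose by 2.06 (SE 0.30) and Atp6v0b by 1.19 (SE 0.11), while Ctsa fell by 0.68 (SE 0.12). Neu1 lies in the same chromosome 17 segment as Tap1, Tap2 and Tapbp. Uchl1, a ubiquitin hydrolase abundant in neurons, rose 8.27-fold from 632 to 5226 CPM, and Fstl1 fell by 0.94 (SE 0.10) from 25998 to 13513 CPM. Cytosolic ribosomal protein genes were lower in 12 of 74 members and higher in 0 (median -0.31, camera adjusted p = 0.00167, and adjusted p = 0.464 with an estimated correlation). This list did not pass fry (adjusted p = 0.159). Of all 10194 tested genes 1328 were lower, so the share of members called lower was close to that of all genes.

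A total of 22 genes rose past the threshold from a control mean under 1 CPM to 20 CPM or more, 6 of them from 0 counts, and 0 genes fell in the mirror way. Read-through from a neighbour would need a risen gene upstream on the same strand within 100 kb that gained as many CPM, and 3 of the 22 (13.6%), Fam57b, H2-Q7 and Ppfia3, have one. Near-identical copies exist for the 3' ends of 2 of the 22 (9.09%), Prr18 and H2-Q7. Cells of the 7 other types listed, pericytes left out, would bring their own markers, and of 58 such markers under 1 CPM in control 0 reached 20 CPM in trSrebf1, the highest being Slpi at 10.2 CPM. These values argue against same-strand read-through, copies that match over 100 or more bases and those 7 types for the group as a whole. Whether the assay captures each of the 58 markers was not tested, so for the 7 types this holds only for markers that it can count. Exon overlaps on the opposite strand were searched only for genes named by the rule, and the use of strand is not given. Nrarp has such an overlap, and Aldoa, which gained 2639 CPM, overlaps Fam57b, which gained 25.6 CPM, over 25 bases. Whether tags from the opposite strand account for the rises was not tested. Matches under 100 bases, which a short tag could share, were not searched for. Opposite-strand tags and short matches stay open, as do cells of types outside the lists, the origin of the cultures, retroviral insertions and a response to trSrebf1. The last is a candidate explanation found and tested on the same data.

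The contractile list fell with a median of -0.92, a camera call that was lost with an estimated correlation (adjusted p = 0.122). Without Ctsd, and scaled to the remaining counts, the median was -0.90, and after a smooth trend on GC content and transcript length was removed, with values for all 28 members, it was -1.18, so neither the counts taken by Ctsd nor such a trend accounts for the fall. Fewer fibroblasts among the sorted cells would lower abundant matrix genes alike. Of the 12 that averaged 1000 CPM or more, 8 (66.7%), or 7 on residual degrees of freedom alone, had a 95% interval above the contractile median. Among the 12, Col1a1 and Col5a1 stood at 0.12 (SE 0.10) and 0.14 (SE 0.10), while Dcn stood at -1.13 (SE 0.10), below that median. The share above the median argues against fewer fibroblasts as the whole cause. Over all 48 matrix genes, compared before the abundant ones were, the shares were 56.2% and 50%, the latter on residual degrees of freedom and computed first. With more than 50% asked for on both, that first comparison was undecided. The argument thus rests on the abundant genes alone, which were picked out afterwards. A smaller share of contractile cells among the fibroblasts, a change in pericytes, whose markers moved both ways, and a response to trSrebf1 stay open.

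Of 14 tested MHC class I heavy chain genes 11 rose and 0 fell, with a median of 3.86, also with H2-Q9, which had 0 control counts, at its bound of at least 16.6-fold (camera adjusted p = 6.93e-19, and adjusted p = 0.0317 with an estimated correlation). H2-K1 rose by 3.76 (SE 0.13) to 341 CPM, whereas H2-T22, H2-T10 and H2-T23 did not pass the threshold, with log2 fold changes of -0.21 (SE 0.17), -0.31 (SE 0.24) and 0.26 (SE 0.26). Of the 8 risen genes that could be searched (3 could not), 7 match another heavy chain gene in their 3' ends and 1, H2-Q10, does not, so how many genes of the family rose cannot be told apart from tags shared between copies. Of 83 other tested genes on chromosome 17 between 33 and 38 Mb 32.5% passed the threshold, 1.08 times the share of all tested genes. A segment that differs between the donor cells need not move most of its genes, so it cannot be told apart from a response to trSrebf1, and both remain open.

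With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3083 genes past the threshold and the highest other split 0, with 1 of 10 splits as large. For gene lists at the preset correlation the real split gave 12 and the highest other split 12, with 3 of 10 splits as large. The other splits mix both groups on each side. They keep part of the group difference, which can move lists, and widen the spread within each side, which hinders calls of genes. Neither count of the other splits is therefore the level that chance alone gives, and no conclusion is drawn from them.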
